A study of Homo sapiens with 48 samples.

How the data were processed

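Polyadenylated RNA was sequenced with strand-specific libraries from A382, an established human glioblastoma cell line. Of the 48 libraries, 44 came from cells carrying guide RNAs, collected at day 9, and 4 came from cells treated with doxycycline for 2 days. The guide RNA libraries held 8 libraries of 4 non-targeting control guides (sgNeg1 to sgNeg4, 2 replicates each), 4 libraries each for BRD8 and for H2AZ (2 guides, 2 replicates each) and 2 libraries, 1 per guide, for each of 14 other subunits of the EP400/TIP60 complex. The doxycycline libraries were 2 of a control vector and 2 of an inducible p53 vector. Groups were taken from the sample labels. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

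The authors deposited 1 table of FPKM values (fragments mapped to a gene, scaled by transcript length and by library depth) for 19102 genes and 48 libraries. TopHat2, Cufflinks, Cuffdiff and the hg19 genome build are named per the submitters' processing notes, without versions or roles. No counts are in the table, so depth was read from the steps between low values: 1 FPKM stood for 4.3 to 21.3 fragments per kilobase of transcript in the different libraries. Columns were matched to libraries by name, and 0 columns belonged to other samples. The table gives no coordinates, and none are printed.

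Empty columns split the table into 5 sections, and the values showed that each had been normalized on its own: sgNeg1 with BRD8 (6 libraries), sgNeg2 with EP400, TIP60, ACTL6A, MRGBP, ING3, TRRAP, DMAP1, GAS41, MEAF6 and VPS72 (22), sgNeg3 with MORF4L1, MORF4L2, RUVBL1 and RUVBL2 (10), sgNeg4 with H2AZ (6), and the doxycycline libraries (4). Relative to each other, the first 4 sections had scale factors of 0.386, 1.27, 1.3 and 1.65. The design fixed before the data were examined compared each knockout with all 8 sgNeg libraries. Because a test across separately normalized sections would measure their scale, each knockout was instead compared with the sgNeg pair of its own section, which had been planned as an alternative. The fit against all 8 is reported as an alternative.

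The columns of MEAF6 guide 2 and VPS72 guide 2 held identical values in all 19102 genes, 14007 of them above 0. Both labels cannot be right, so this column was left out of both comparisons, each of which then rested on 1 library, and 46 columns entered the fits.

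Values were analysed as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 libraries of a section were tested with limma 3.58.1 in R 4.3.3 (linear model, 1 level per target, empirical Bayes with an intensity trend, two-sided), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. Errors are standard errors (SE) for log2 fold changes and standard deviations (SD) for FPKM. MEAF6 and VPS72, with 1 library each, borrowed their spread from the other libraries of the section.

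A set of 28 gene lists was fixed before the data were examined. Each was tested with limma's camera against all other genes (preset correlation 0.01, and again with an estimated correlation), with Benjamini-Hochberg adjustment over the lists of a comparison. The p53 target list was adjusted over the 16 knockouts. Lists with fewer than 3 tested members got no test. The exact permutation test of the list's mean per library cannot go below 0.0667 with 4 libraries against 2, or below 0.167 with 2 against 2. Where a list's call under the preset correlation was lost with the estimated one, both are given or the loss is stated. In the 16 knockouts every list that passed lost its call in this way. Such a loss does not by itself show that list members are correlated. For the p53 list in H2AZ the estimated correlation was 0.01 after rounding, equal to the preset. Camera's unadjusted p still went from 0.000135 to 0.0186.

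The genes named were set by a rule fixed before the data were examined. For BRD8, H2AZ and p53 induction these were the targeted gene, CDKN1A and MDM2, the 10 called genes with the largest rise and the 10 with the largest fall, and up to 4 called members with the smallest adjusted p for each list described. The largest changes were taken among genes with a mean FPKM of at least 5 in the higher group and with all libraries of the group on 1 side of all controls. For each other knockout they were the targeted gene, CDKN1A, MDM2 and the largest rise and fall. For BRD8 against p53 induction they were the 10 genes changed the same way in both with the largest smaller change.

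On simulated values with known changes, 97% of genes changed by 1 log2 unit were recovered in the BRD8 comparison, 87.9% in H2AZ, 80.3% in EP400, 78.8% in RUVBL1 and 92.4% in p53 induction. At a change of 0.5 log2 units the shares were 86.8%, 32.4%, 23.5%, 27.9% and 55.9%. Changes were planted only in genes above the lowest expression levels, so recovery among weakly expressed genes was not measured. The alternatives tried were a pseudocount of 0.1, no filter on low values, rescaling of each library by its median ratio, a replicate block, other control sets, a spread shared over more or fewer libraries, each guide alone and leaving out each library in turn. After the data had been seen, a removal of each library's trend with transcript length, control sets after rescaling, a shared spread on the genes of the main fit and both assignments of the duplicated column were added. Transcript lengths and exon numbers came from a GENCODE annotation, matched by symbol, and 96.9% of genes had a length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for preparation and plots.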

Results

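The libraries address which subunits of the EP400/TIP60 chromatin complex, a histone acetyltransferase and histone exchange complex, change p53 target genes when lost in a glioblastoma line, and how these changes relate to those from expressing p53 itself. BRD8 is a bromodomain subunit of this complex, and H2AZ is the histone variant that it exchanges into chromatin. Between 10503 and 11853 genes had an FPKM of at least 1 in each library outside the sgNeg1 and BRD8 section, against 8081 to 8158 within it. At an FPKM of 1, a kilobase of transcript was covered by 17.3 to 21.3 fragments in the sgNeg1 and BRD8 section, 8.1 to 18.6 in the sgNeg2 section, 12.3 to 16.2 in the sgNeg3 section, 4.3 to 7.5 in the sgNeg4 and H2AZ section and 11.4 to 12.3 in the doxycycline section, figures that each follow the FPKM scale of their section.

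The sgNeg1 and BRD8 libraries differed from all others in which genes they registered. Between 18 and 21 single-exon genes reached an FPKM of 1 there, against 169 to 221 in the other libraries, sgNeg1 and BRD8 alike. Relative to the other sgNeg pairs, the sgNeg1 values of 89 single-exon genes had a median log2 difference of -2.12, and those of 876 genes with 21 to 118 exons a median of 0.60. RPS27, RPS28, RPL21 and RPL36A averaged 1160, 601, 347 and 300 FPKM in sgNeg1 and reached at most 4.11, 1.73, 1.17 and 7.07 in other sections. BRD8 folds therefore refer to sgNeg1 only, and FPKM levels are not comparable between sections.

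**Figure D1:**
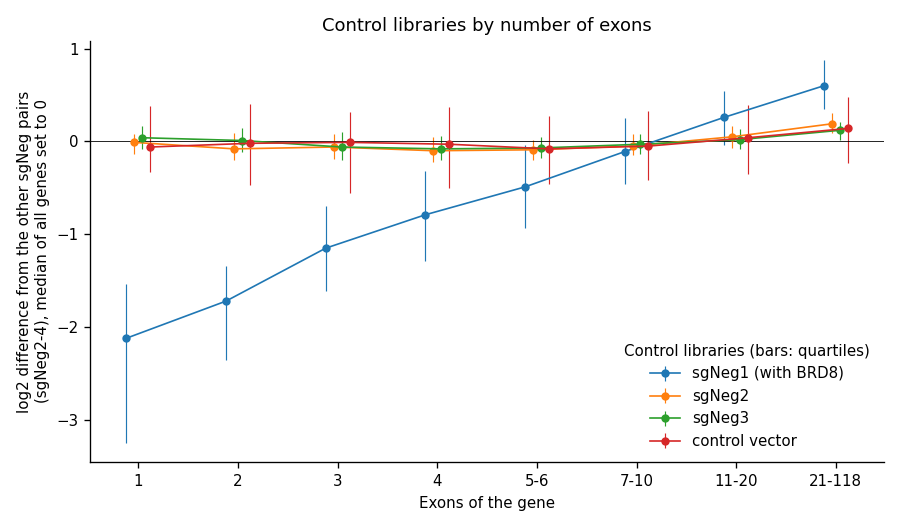
Median log2 difference (points) with quartiles (bars) of the sgNeg1, sgNeg2, sgNeg3 and doxycycline control vector pairs from the other pairs among sgNeg2 to sgNeg4, on the y axis with the median of all genes set to 0, against the number of exons per gene on the x axis. The sgNeg1 line climbs from -2.12 at 1 exon to 0.60 at 21 or more exons, while the other 3 lines stay between -0.10 and 0.19.

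The targeted mRNA was lower in most knockouts. H2AFZ, a gene of H2A.Z besides H2AFV, fell to 18.6% of its control, from 647 ± 169 (n = 2) to 120 ± 3.48 FPKM (n = 4). BRD8 mRNA fell to 43.1%, from 13.5 ± 0.17 (n = 2) to 5.80 ± 0.611 FPKM (n = 4). RUVBL2 fell to 28.5%, ACTL6A to 37.5%, RUVBL1 to 40.1%, YEATS4 (the gene of GAS41) to 45.4%, EP400 to 48.5% and KAT5 (the gene of TIP60) to 51.5%, all called by limma. DMAP1 stood at 40.5% (adjusted p = 0.0642), MRGBP at 51% (0.0948), ING3 at 65.9% (0.274), MEAF6 at 68.2%, VPS72 at 74.7% and TRRAP at 82.3% (0.44), none of them past the threshold. MORF4L2 stood at 92.8% and MORF4L1 at 103.4% of control. A frameshift need not lower the mRNA, so a level near control does not show that editing failed. In the duplicated column that carries the labels of MEAF6 guide 2 and VPS72 guide 2, MEAF6 was at 9.4 and VPS72 at 17.2 FPKM, against 8.22 and 31.9 in the sgNeg2 pair.

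**Figure D2:**
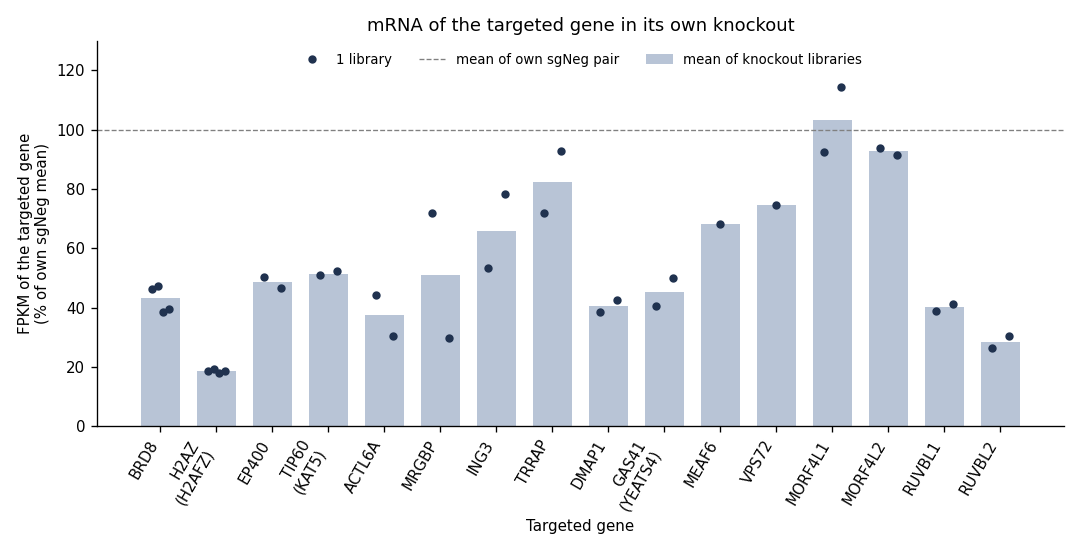
FPKM of the targeted gene as a percentage of the mean of its own sgNeg pair (y axis) in each of 16 knockouts (x axis), with bars for the mean and points for single libraries. The bars run from 18.6% for H2AFZ to 103.4% for MORF4L1.

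Against the sgNeg1 pair, the 1 control guide of its section, BRD8 knockout had lower mitotic and extracellular matrix genes and higher ribosomal protein genes, some p53 targets and targets of YAP. Of 35 genes of G2/M and mitosis, 34 fell and 1 rose, with a mean log2 fold change of -0.66. The falls included PTTG1 (securin, -1.33 ± 0.15), CCNB2 (cyclin B2, -1.18 ± 0.16), KIF2C (-0.96 ± 0.13) and CDC25C (-0.79 ± 0.09). Of 21 collagen and matrix genes, 19 fell and 0 rose (mean -0.73), and both lists had the same counts adjusted over the list alone. COL3A1 (-2.13 ± 0.10), SPARC (-1.43 ± 0.11), the laminin chain LAMB1 (-0.98 ± 0.07) and TNC (tenascin C, -0.82 ± 0.07) were among those that fell. Of 36 tested p53 target genes, 18 rose and 4 fell (19 and 4 adjusted over the list alone), with a mean of 0.20. Of 11 tested p53 cell death genes, 4 rose and 2 fell (the same adjusted over the list alone), and that list did not pass (mean -0.01, adjusted p = 0.886). GADD45A rose by 1.17 ± 0.11, GDF15 by 0.92 ± 0.09, MDM2, the ubiquitin ligase of p53, by 0.77 ± 0.08 and SESN2 by 0.75 ± 0.09. SESN2 is also a member of the ATF4 and unfolded protein response list, whose mean was higher in BRD8 knockout too. CDKN1A, the cell cycle inhibitor p21, rose by 0.38 ± 0.07, from 13 ± 0.245 (n = 2) to 17.2 ± 1.23 FPKM (n = 4; adjusted p = 0.00179).

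By limma, 3885 of 8458 tested genes were called in BRD8 knockout, 2047 higher and 1838 lower, of which 68 rose and 71 fell by at least 2-fold. The largest rises were in IL13RA2, a decoy receptor of interleukin 13 (2.13 ± 0.20), FST (follistatin, 1.99 ± 0.08), MGST1 (a microsomal glutathione transferase, 1.97 ± 0.13), HMOX1 (heme oxygenase, 1.96 ± 0.14), RND3 (1.91 ± 0.08), SPP1 (osteopontin, 1.91 ± 0.18), OSGIN1 (1.90 ± 0.17), MT2A (a metallothionein, 1.77 ± 0.13), FTH1 (ferritin heavy chain, 1.75 ± 0.11) and TXNRD1 (thioredoxin reductase, 1.70 ± 0.10). FTH1 and MT2A belong to families with near-identical copies, and their values are uncertain for that reason. The largest falls were in SLC14A1, a urea transporter (-2.54 ± 0.13), COL3A1, COL23A1 (-2.10 ± 0.07), ADAMTS14 (a procollagen peptidase, -1.98 ± 0.14), ECM1 (-1.95 ± 0.10), SNED1 (-1.84 ± 0.11), HOMER2 (-1.82 ± 0.09), NBL1 (-1.73 ± 0.13), SAT1 (-1.69 ± 0.10) and COL1A2 (-1.61 ± 0.19). All 20 had adjusted p-values of 0.000149 or lower.

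Further groups moved in the BRD8 libraries. Of 46 cytosolic ribosomal protein genes, 32 rose and 0 fell (38 and 0 adjusted over the list alone; mean 0.27), among them RPS12 (0.88 ± 0.09), RPL38 (0.46 ± 0.07), RPL8 (0.45 ± 0.06) and RPL6 (0.38 ± 0.06). Of 13 YAP/TEAD targets, 9 rose (9 adjusted over the list alone; mean 0.49), including ANKRD1 (1.06 ± 0.09), CRIM1 (0.81 ± 0.07), ASAP1 (0.76 ± 0.07) and CTGF (0.68 ± 0.07). Of 20 interferon-stimulated genes, 7 fell and 0 rose (the same adjusted over the list alone; mean -0.38), with ISG15 at -1.40 ± 0.22, USP18 at -0.84 ± 0.14, IRF7 at -0.72 ± 0.10 and DDX58 at -0.66 ± 0.10. Of 17 tested subunits of the complex, BRD8, ACTL6A (-0.22 ± 0.06) and MORF4L2 (-0.26 ± 0.07) fell and YEATS4 (0.18 ± 0.07) rose over all genes, against 3 lower and 0 higher adjusted over the list alone, and the list as a whole did not pass (mean -0.09, adjusted p = 0.245).

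In camera with the preset correlation, adjusted p was 1.46e-10 for the G2/M list, 1.13e-09 for collagen and matrix, 7.98e-08 for ribosomal proteins, 0.000125 for YAP/TEAD, 0.0024 for interferon-stimulated genes and 0.00783 for p53 targets. None of the 6 calls held: adjusted p = 0.374 with an estimated correlation for G2/M, for collagen and matrix and for YAP/TEAD, 0.469 for ribosomal proteins, 0.521 for interferon-stimulated genes and 0.39 for p53 targets. The p53 list mean was higher in 4 of 4 BRD8 libraries than in both sgNeg1 libraries (3.04 ± 0.04 against 2.83 ± 0.01 on the log2 scale), which gave an exact two-sided permutation p of 0.0667, the smallest this design allows. The count of called genes was 2007 with a spread shared over all guide RNA libraries, 1865 when the genes tested were also chosen over all of them, 2325 without sgNeg1 replicate 1 and 2567 without sgNeg1 replicate 2. Against all 8 sgNeg libraries, which mixes sections, 10497 genes were called and the p53 list mean was -1.31, and after rescaling these were 8453 and -0.19.

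Against the sgNeg4 pair, also the 1 control guide of its section, H2AZ knockout had higher genes of the ATF4 and unfolded protein response and lower matrix and interferon-stimulated genes. Of 24 ATF4 and unfolded protein response genes, 14 rose and 1 fell (16 and 3 adjusted over the list alone), with a mean of 0.60. Among them were TRIB3 (a pseudokinase induced by ATF4, 1.78 ± 0.10), the serine synthesis enzyme PSAT1 (1.66 ± 0.09), asparagine synthetase ASNS (1.38 ± 0.10) and SESN2 (1.24 ± 0.09). Of 21 collagen and matrix genes, 9 fell and 0 rose (12 and 1 adjusted over the list alone; mean -0.36), including COL3A1 (-1.05 ± 0.15), TIMP3 (-0.95 ± 0.09), COL1A2 (-0.74 ± 0.11) and COL4A1 (-0.61 ± 0.11). Of 17 interferon-stimulated genes, 5 fell (6 adjusted over the list alone; mean -0.34), with BST2 at -1.20 ± 0.23, IFI6 at -0.97 ± 0.23, IFIT1 at -0.66 ± 0.15 and ISG15 at -0.52 ± 0.11. Of 13 YAP/TEAD targets, 3 rose, CYR61 (0.78 ± 0.10), AJUBA (0.73 ± 0.09) and AMOTL2 (0.52 ± 0.11), against 8 adjusted over the list alone (mean 0.37).

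By limma, 667 of 11087 tested genes were called in H2AZ knockout, 288 higher and 379 lower. The largest rises were in HMOX1 (1.92 ± 0.13), TRIB3, NUPR1 (a stress-induced nuclear protein, 1.74 ± 0.12), GDF15 (1.68 ± 0.09), PSAT1, EDN1 (endothelin 1, 1.61 ± 0.12), INHBE (1.60 ± 0.10), SLC7A5 (an amino acid transporter, 1.57 ± 0.15), STC2 (1.54 ± 0.10) and NNMT (1.47 ± 0.20). Besides H2AFZ (-2.40 ± 0.14), the largest falls were in SCG2 (-1.89 ± 0.15), SERPINF1 (-1.81 ± 0.14), CYB5R2 (-1.60 ± 0.19), KIAA0040 (-1.46 ± 0.09), C7 (-1.44 ± 0.12), LMO2 (-1.40 ± 0.16), S100A4 (-1.38 ± 0.21), CADM4 (-1.36 ± 0.15) and TPPP3 (-1.32 ± 0.24). CDKN1A (0.15 ± 0.10, adjusted p = 0.456) and MDM2 (0.36 ± 0.11, adjusted p = 0.0803) did not pass. The p53 target list had a mean of 0.16 (adjusted p = 0.000309, and 0.0992 with an estimated correlation), and 2 of its 43 members, GDF15 and SESN2, were called, against 6 higher and 1 lower adjusted over the list alone. SESN2 stands on the ATF4 and unfolded protein response list as well, so its rise does not separate the 2 lists. Whether the rise of GDF15 came from p53 or from another response was not tested. Of 5 tested H2A variant genes, H2AFZ alone was called over all genes, against 2 lower adjusted over the list alone. The test of that list is not used, because it contains the targeted gene.

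For the other H2AZ lists, camera gave adjusted p = 1.72e-12 for ATF4 and the unfolded protein response, 1.11e-06 for collagen and matrix and for YAP/TEAD, and 6e-04 for interferon-stimulated genes. With an estimated correlation these were adjusted p = 0.0884, 0.272, 0.272 and 0.0967, and none held. The 35 G2/M genes had a mean of -0.05 with 0 called by limma over all genes and 0 adjusted over the list alone (adjusted p = 0.436). The H2AZ count moved from 667 to 324 to 366 without H2AZ guide 1 replicate 2, guide 2 replicate 1 or guide 2 replicate 2, and to 1176 without sgNeg4 replicate 2. It was 146 with guide 1 alone, 247 with guide 2 alone, 1050 with a spread shared over all guide RNA libraries, 1069 when the genes tested were also chosen over all of them, 1113 with the length trend removed, and 4662 or, after rescaling, 1828 against all 8 sgNeg libraries.

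Across the 16 knockouts, the p53 target list was higher, at an adjusted p under 0.05, in 10. Its mean log2 fold change was 0.54 in RUVBL2 (adjusted p = 1.23e-08), 0.48 in RUVBL1 (1.82e-07), 0.30 in GAS41 (5.15e-09), 0.20 in ING3 (2.09e-06) and in BRD8 (0.00783), 0.17 in ACTL6A (9.67e-05), 0.16 in H2AZ (0.000309), 0.15 in DMAP1 (7.09e-05), 0.10 in MRGBP (0.0322) and 0.07 in EP400 (0.0462). With an estimated correlation none of the 10 held: adjusted p = 0.0525 with an estimated correlation for RUVBL1 and RUVBL2, 0.0992 for H2AZ, 0.309 for GAS41, 0.39 for ING3 and BRD8, 0.42 for ACTL6A and DMAP1 and 0.675 for MRGBP and EP400. The list mean was 0.06 in MORF4L2 (adjusted p = 0.244), 0.04 in MORF4L1 (0.141), -0.04 in MEAF6 (0.91) and -0.02 in VPS72 (0.933). In TIP60 (mean -0.03, adjusted p = 0.723) and TRRAP (mean -0.02, adjusted p = 0.91) the test pointed up while the mean and median were below 0. Without EP400 guide 1 the EP400 adjusted p was 0.0698, without DMAP1 guide 1 the DMAP1 mean was 0.04 (0.103), without MRGBP guide 2 the MRGBP adjusted p was 0.543, and without sgNeg2 replicate 1 those of EP400 and MRGBP were 0.169 and 0.24. Without guide 2 the list mean was 0.11 in TIP60 and 0.08 in TRRAP, on the other side of 0. In ACTL6A the list mean was 0.07 without guide 2 and 0.26 without guide 1.

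In knockout of RUVBL1 or RUVBL2, the paired ATPases of the complex, many single p53 targets passed by limma. Of 45 tested members, 22 rose and 2 fell in RUVBL1 knockout (24 and 4 adjusted over the list alone), and 28 rose and 3 fell in RUVBL2 knockout (30 and 3). CDKN1A rose by 1.20 ± 0.15 in RUVBL1 and by 1.07 ± 0.15 in RUVBL2 (adjusted p = 0.0012 and 0.00108; n = 2 against 2). MDM2 rose by 0.90 ± 0.11 and 1.08 ± 0.11. CDKN1A and MDM2 passed the threshold in none of the 12 remaining knockouts outside BRD8 and H2AZ; in GAS41, for example, they stood at 0.65 ± 0.23 (adjusted p = 0.176) and 0.70 ± 0.18 (0.0692). Over the 16 knockouts, GDF15 was called higher in 5, and CYFIP2, EDA2R, GADD45A, PHLDA3, PMAIP1, RRM2B and SESN2 in 4 each. Other members went the other way. TP53I3 was called lower in 4 and APAF1 in 3, both higher in 0. PANK1, PLK2 and SESN1 were called lower in 2 each, with PLK2 and SESN1 higher in 1. Knockouts of a section share their sgNeg pair, so these counts are not independent. For a joint fit each section was divided by its scale factor, which leaves the dependence of the BRD8 section on exon number in place. Changes at low levels are understated on the log2(FPKM + 1) scale, so part of a difference between knockouts may stem from their sections. The BRD8 change of the list was then compared with those of the others over 36 members in tests that share no control. It was smaller than in RUVBL2 by -0.32 (adjusted p = 0.000224) and in RUVBL1 by -0.28 (0.0086), and larger than in MEAF6 by 0.26 (0.0297) and in VPS72 by 0.21 (0.0417). None of the 4 differences held, with adjusted p = 0.87 with an estimated correlation, and the other 11 did not pass.

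TIP60 knockout changed 4782 of 11382 genes, with 36.7% of calls higher, or 48.3% after rescaling. STRA6, a receptor for retinol-binding protein, rose by 5.35 ± 0.30, from 1.62 to 107 FPKM, and KIAA0040 fell by 3.81, to 0.504 FPKM. RUVBL2 changed 3698 and RUVBL1 3077 of 11063 genes, with SDCBP2 the largest rise (2.86 ± 0.15 and 2.73 ± 0.15) and KIAA0040 the largest fall (-3.45 ± 0.18 and -3.03 ± 0.18) in both. These counts do not rank the knockouts of different sections, since fits over the libraries of each comparison alone gave 3428 calls in TIP60, 6776 in RUVBL2 and 6077 in RUVBL1. TRRAP changed 1621 genes, with KRTAP2-3, a keratin-associated protein gene, at 4.59 ± 0.48 and PTCD1 at -2.72 ± 0.40, and EP400 changed 436, with KRTAP2-3 at 2.97 ± 0.48 and KIAA0040 at -1.96 ± 0.41. GAS41 changed 107 genes (KRTAP1-5, 2.92 ± 0.56, and KIAA0040, -1.89 ± 0.41), ACTL6A 89 (KCNG1, a potassium channel subunit, 1.54 ± 0.23, and C1orf54, -2.16 ± 0.47) and MRGBP 30 (VGF, 2.08 ± 0.22, and the readthrough gene TGIF2-C20orf24, -3.33 ± 0.44). In ING3 the 3 called genes rose, with IL1B the largest (2.22 ± 0.23). PTCD1 and TGIF2-C20orf24 overlap neighbouring genes and are uncertain. By limma, 0 genes were called in DMAP1, MEAF6, VPS72, MORF4L1 and MORF4L2, where 1021, 413, 401, 85 and 230 had an unadjusted p under 0.05. Leaving out any 1 of the 4 libraries took the EP400 count to between 9 and 48, RUVBL1 to 859 to 1987 and RUVBL2 to 1652 to 1848. It took ACTL6A to 0 to 380, MRGBP to 2 to 238, GAS41 to 0 to 25, and TRRAP to 72 without guide 2, 386 without sgNeg2 replicate 1 and 647 without sgNeg2 replicate 2. DMAP1 had 40 calls without guide 2 and MORF4L2 had 1315 without guide 1.

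Some gene lists passed in these knockouts, and differences between the knockouts were not tested. G2/M and mitosis genes fell in RUVBL1 (33 of 35, and 34 adjusted over the list alone; mean -1.0, adjusted p = 5.85e-16) and in RUVBL2 (34 of 35 either way; mean -1.39, adjusted p = 2.72e-18), and in TRRAP 6 of 35 fell over all genes and 11 adjusted over the list alone (mean -0.46). The same list passed as higher in TIP60 (8 higher and 1 lower, and 7 and 1; mean 0.26, adjusted p = 0.00264) and, with 0 members called over all genes or over the list alone, in DMAP1 (0.27, 7.03e-09), VPS72 (0.25, 3.35e-07), EP400 (0.16, 0.00174), ACTL6A (0.14, 0.00267) and MRGBP (0.14, 0.0171). It passed as lower, again with 0 called, in MORF4L2 (-0.15, 4.17e-05) and MORF4L1 (-0.08, 0.046). These 8 were lost, with adjusted p = 0.943, 0.733, 0.811, 0.838, 0.697, 0.999, 0.712 and 0.819 with an estimated correlation, in that order. The knockouts in which the G2/M list passed as higher share the sgNeg2 pair as control and are not independent. Collagen and matrix genes fell in RUVBL1 (12 of 21, and 16 adjusted over the list alone; mean -0.79), RUVBL2 (13, and 15; mean -0.86) and TRRAP (10 lower and 2 higher, and 12 and 3; mean -0.54). Neural progenitor genes fell in RUVBL1 (5 of 7 either way; mean -0.83) and in RUVBL2 (5 of 7, and 6 adjusted over the list alone; mean -1.0). In TIP60, values of histone genes of the replication-dependent class rose (9 of 12 either way, mean 1.23, camera adjusted p = 5.48e-05). Only polyadenylated RNA was sequenced, so histone mRNA without a poly(A) tail was not measured. Also higher in TIP60 were 17 of 34 G1/S and DNA replication genes (18 adjusted over the list alone, mean 0.45) and 9 of 14 YAP/TEAD targets (9 either way, mean 0.89). Immediate early genes rose in TRRAP (8 of 17, and 9 adjusted over the list alone; mean 0.90, adjusted p = 2.46e-06). Cholesterol synthesis genes had a mean of 0.40 in DMAP1 (adjusted p = 6.89e-15) with 0 called by limma over all genes and 12 of 23 higher adjusted over the list alone. None of the others held: adjusted p = 0.26 with an estimated correlation for the G2/M and neural progenitor lists in RUVBL1, 0.263 for both in RUVBL2, 0.64 for G2/M in TRRAP, 0.456 for collagen in RUVBL1, 0.384 in RUVBL2 and 0.598 in TRRAP, 0.709 for the 3 TIP60 lists, 0.598 for immediate early genes in TRRAP and 0.216 for cholesterol synthesis in DMAP1.

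**Figure D3:**
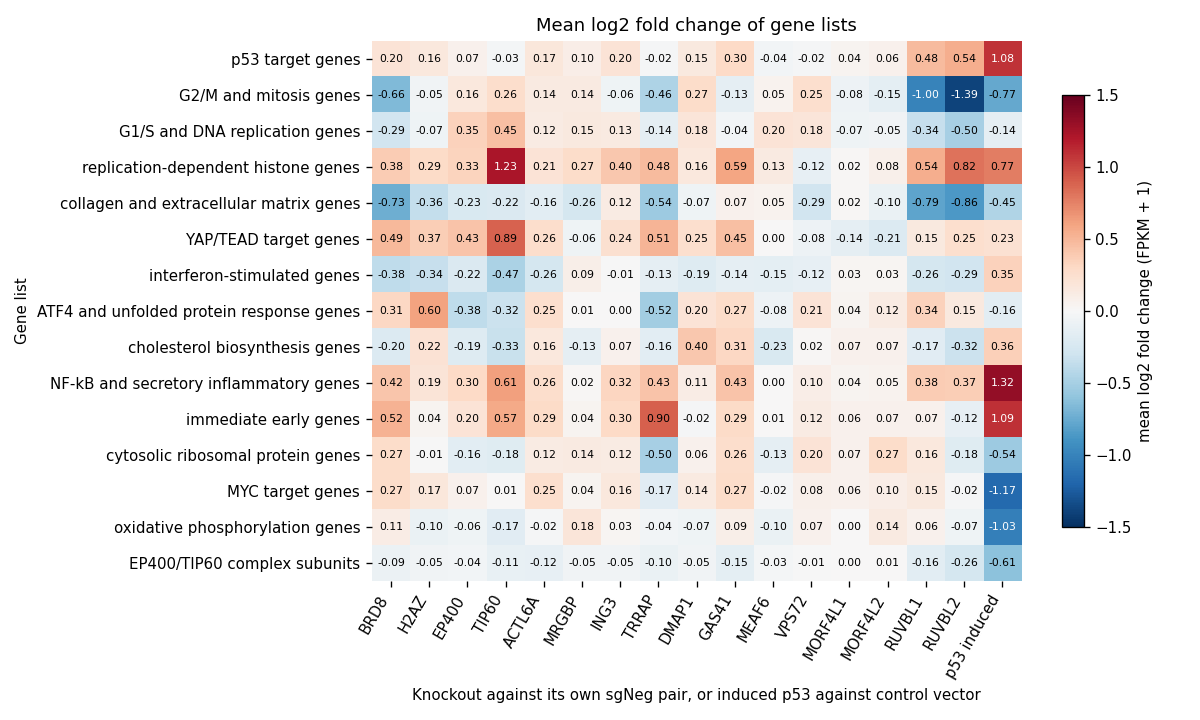
Mean log2 fold change (colour and number) of 15 gene lists (y axis) in 16 knockouts against their own sgNeg pair and in induced p53 against control vector (x axis). The G2/M list is lowest in RUVBL2 (-1.39) and RUVBL1 (-1.0), and the p53 target list is highest in induced p53 (1.08).

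Changes in BRD8 knockout ran in parallel with those of several other knockouts that were tested against different controls. Across genes, which are not independent replicates, log2 fold changes in BRD8 correlated with those in H2AZ (Pearson r = 0.54, Spearman rho = 0.48 over 8241 genes), RUVBL2 (0.49 and 0.42), RUVBL1 (0.48 and 0.41), GAS41 (0.47 and 0.44) and TIP60 (0.42 and 0.37). They did not follow those in MORF4L2 (0 and 0.01) or MORF4L1 (-0.15 and -0.15). With H2AZ, 184 genes were called higher in both against 58.2 expected for independent lists, and 183 were called lower in both against 59.4 expected. With RUVBL2, the corresponding numbers were 494 against 270.1 and 780 against 335.5.

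**Figure D4:**
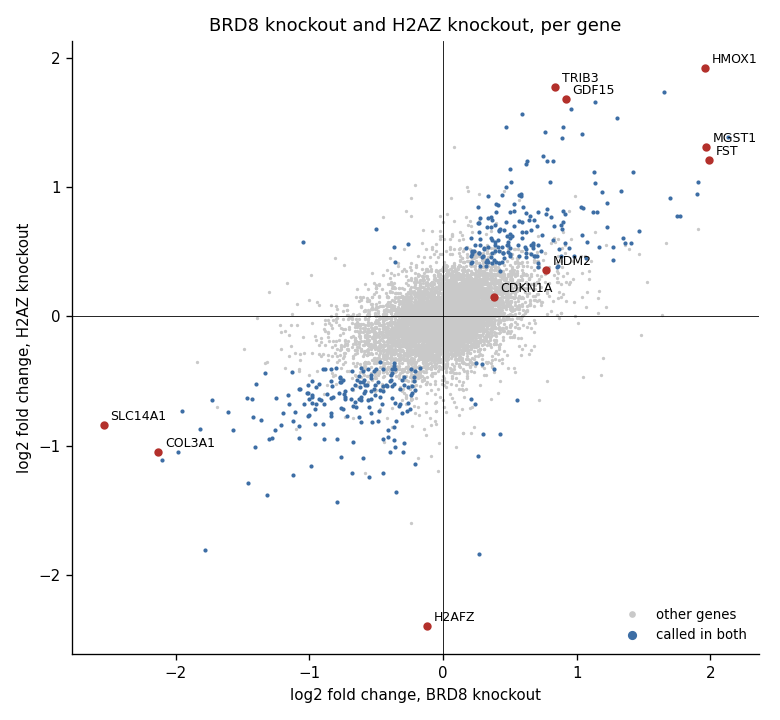
Log2 fold change of each gene in BRD8 knockout (x axis) and in H2AZ knockout (y axis), with genes called in both in blue and a few named genes in red. Most blue points lie where both are higher (184 genes) or both are lower (183 genes), and HMOX1 stands at 1.96 and 1.92.

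Induced p53 raised cell death and inflammatory genes and lowered MYC targets and genes of oxidative phosphorylation within 2 days. Of 44 tested p53 target genes, 38 rose and 3 fell (the same numbers adjusted over the list alone; mean 1.08), among them SUSD6 (3.38 ± 0.06), CDIP1 (3.29 ± 0.05) and APAF1 (3.18 ± 0.07). MDM2 rose by 2.36 ± 0.06 to 141 ± 7.82 FPKM (n = 2), and CDKN1A by 1.66 ± 0.04 to 800 ± 31.6 FPKM (n = 2). All 13 tested p53 cell death genes rose (13 adjusted over the list alone; mean 1.70), including PIDD1 (3.41 ± 0.06). Of 15 inflammatory genes of the NF-kB list, 10 rose and 2 fell (the same adjusted over the list alone; mean 1.32), with MMP1 (a collagenase, 5.05 ± 0.11), CCL2 (2.90 ± 0.06), CXCL8 (2.01 ± 0.06) and LIF (1.80 ± 0.04).

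Genes of growth and of the cell cycle fell, and the counts of the MYC, oxidative phosphorylation, G2/M and subunit lists were the same adjusted over the list alone. Of 25 MYC targets, 25 fell (mean -1.17), such as PAICS (-1.91 ± 0.04), HSPD1 (-1.66 ± 0.04), LDHA (-1.54 ± 0.04) and CCT3 (-1.54 ± 0.04). Of 26 oxidative phosphorylation genes, 25 fell and 1 rose (mean -1.03), including ATP5B (-1.81 ± 0.04), COX7B (-1.59 ± 0.05), UQCRC2 (-1.53 ± 0.04) and ATP5C1 (-1.52 ± 0.04). Of 35 G2/M and mitosis genes, 32 fell and 3 rose (mean -0.77). CENPF (-1.76 ± 0.09), ANLN (-1.61 ± 0.07) and CDC20 (-1.26 ± 0.06) fell, whereas PTTG1 rose by 2.95 ± 0.07. Of 18 subunits of the EP400/TIP60 complex, 14 fell and 0 rose (mean -0.61), with ACTL6A at -1.38 ± 0.05, MORF4L2 at -1.35 ± 0.04, RUVBL2 at -1.22 ± 0.05 and RUVBL1 at -1.18 ± 0.05.

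By limma, 10293 of 12203 genes were called after p53 induction, 4591 higher and 5702 lower, of which 2395 rose and 1325 fell by at least 2-fold. Among the 10 largest rises, the late cornified envelope genes LCE1C (416 and 394 FPKM) and LCE1F (214 and 199), WFDC5 (93.2 and 100) and PLK5 (95.3 and 92.7) were listed at 0 in both control vector libraries. The other 6 were CRYAB, a small heat shock protein (7.10 ± 0.08), PRAP1 (6.77 ± 0.08), TNNT3 (6.68 ± 0.09), LSP1 (6.59 ± 0.08), the protease CTSH (6.34 ± 0.06) and CHRM4 (6.29 ± 0.07). The largest falls were in NPTX2 (-5.43 ± 0.08), PEG10 (-4.80 ± 0.05), S100P (-4.54 ± 0.11), NID2 (-4.07 ± 0.06), INHBE (-3.98 ± 0.08), APOE (-3.86 ± 0.06), PDP1 (-3.83 ± 0.07), IGFBP2 (-3.68 ± 0.12) and NNMT (-3.61 ± 0.07). ATP1B2 was listed at 0 in both induced libraries and at 11.3 and 9.92 FPKM in the controls.

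Camera gave adjusted p = 2.62e-07 for p53 targets, 1.35e-06 for MYC targets, 1.71e-06 for oxidative phosphorylation, 1.93e-05 for p53 cell death genes, 0.000193 for G2/M, 0.00917 for the complex subunits and 0.0122 for the NF-kB list. None held over the 28 lists: adjusted p = 0.338 with an estimated correlation for each of the 7. Taken alone, as fixed in the design, the p53 target list had p = 9.35e-09, and p = 0.0206 with an estimated correlation. This fit had 2 residual degrees of freedom, and the median of all log2 fold changes was -0.13. After rescaling the median was -0.01, and the share of called genes that were higher moved from 44.6% to 50.8%.

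Among genes tested in both, BRD8 knockout at day 9 and p53 induction over 2 days shared no more same-direction calls than independent lists would. Over 8249 genes, their log2 fold changes correlated at r = -0.04 (rho = -0.05), and with the p53 target list left out at -0.04 (-0.06). Genes called higher in both numbered 600 against 599.1 expected, and genes called lower in both 901 against 967.4 expected (Fisher's exact test over genes, adjusted p = 1 and 0.000824). In opposite directions, 1110 were higher in BRD8 and lower with p53 against 1069.7 expected, and 617 were lower in BRD8 and higher with p53 against 541.8 expected. Of 2395 genes that induced p53 raised at least 2-fold, only 933 were tested in the BRD8 section. Of these, 226 were higher and 255 lower in BRD8 knockout (camera, adjusted p = 0.937). Of 1325 that it lowered at least 2-fold, 1027 were tested there, 307 higher and 209 lower (camera, adjusted p = 0.496). The comparison does not cover the genes left untested in that section. Both lists come from the samples of this series. Over the 16 knockouts, the induced list passed in none and the lowered list passed as lower in RUVBL1 (mean -0.19, adjusted p = 0.00403) and RUVBL2 (-0.27, 0.0022), both lost (adjusted p = 0.984 with an estimated correlation). The naming rule took 10 genes that changed the same way in both. HMOX1 (1.96 ± 0.14 in BRD8 and 2.18 ± 0.08 with p53), OSGIN1 (1.90 ± 0.17 and 2.28 ± 0.08), MT2A (1.77 ± 0.13 and 2.31 ± 0.05) and SQSTM1 (1.35 ± 0.10 and 1.58 ± 0.05) rose. COL3A1 (-2.13 ± 0.10 and -2.27 ± 0.09), SERPINF1 (-1.78 ± 0.11 and -2.02 ± 0.09), SPARC (-1.43 ± 0.11 and -1.33 ± 0.05), CFI (-1.41 ± 0.15 and -1.33 ± 0.10), CD55 (-1.36 ± 0.08 and -1.31 ± 0.05) and the desaturase gene SCD (-1.30 ± 0.07 and -1.63 ± 0.06) fell. PTTG1 was among those that moved apart, at -1.33 ± 0.15 in BRD8 knockout and 2.95 ± 0.07 with p53.

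**Figure D5:**
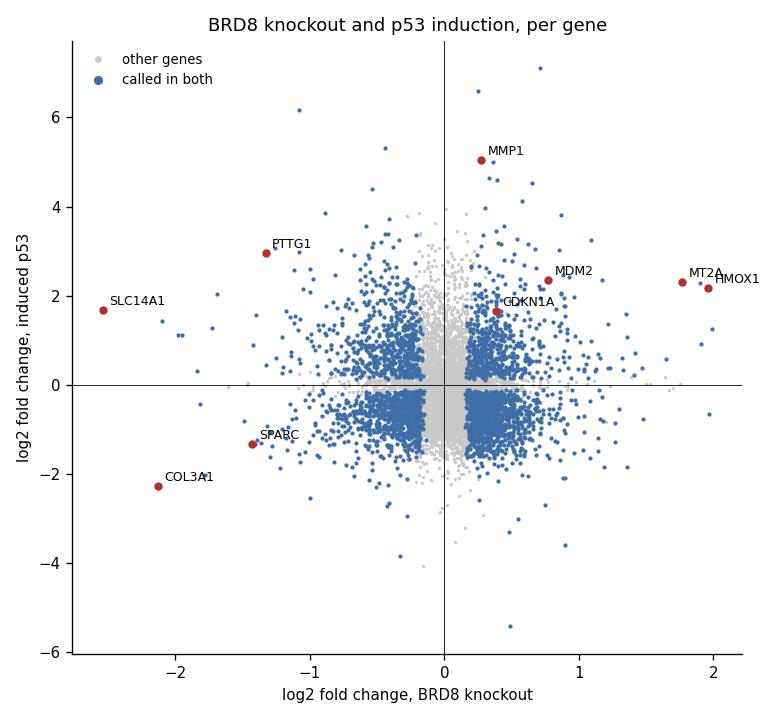
Log2 fold change of each gene in BRD8 knockout (x axis) and with induced p53 (y axis), with genes called in both in blue and a few named genes in red. The points fill all 4 quadrants, with 600 genes higher in both and 901 lower in both.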

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

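The tests of loss of BRD8 and of depth for the exon number pattern, and those of the length trend and of p53 activity for the mitotic genes, were chosen after the result was seen.

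Among the 133 values tested for a library far from the other 3 of its knockout (named genes and list means in BRD8 and H2AZ), 7 stood apart, and chance gives about 1 in 20. CDKN1A was at 19.1 FPKM in BRD8 guide 1 replicate 2 and at 16.5 to 16.8 in the other BRD8 libraries. USP18 was at 1.65 FPKM in BRD8 guide 2 replicate 2, against 2.54 to 2.7. MDM2 was at 37.0 FPKM in H2AZ guide 1 replicate 1, against 44.4 to 45.7. In that same H2AZ library the list means, as log2(FPKM + 1), were 6.03 for H2A variants (5.89 to 5.91 in the others), 6.09 for ATF4 and unfolded protein response genes (6 to 6.01) and 4.02 for epithelial markers (3.93 to 3.94). Astrocyte markers averaged 5.72 in H2AZ guide 1 replicate 2, against 5.78 to 5.79.

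The p53 target list differed between BRD8 and 4 other knockouts by a test of the difference itself, by 0.26 for MEAF6, 0.21 for VPS72, -0.28 for RUVBL1 and -0.32 for RUVBL2, and none of the 4 held (adjusted p = 0.87 with an estimated correlation). Between the 2 BRD8 guides, IL1B was higher with guide 2 by 1.10 ± 0.08 (limma, adjusted p = 0.00155), the 1 gene of 8458 called. The column that carries both the MEAF6 guide 2 and the VPS72 guide 2 labels, which no main comparison used, had short transcripts above long ones by 0.67 log2 units.

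Values of the sgNeg1 and BRD8 libraries depended on exon number. Loss of BRD8 as the cause is excluded by the sgNeg1 libraries, which had at most 20 single-exon genes at an FPKM of 1. Low depth is excluded as well for sgNeg1. From their level in sgNeg2 to sgNeg4, the 89 single-exon genes were each expected to have at least 19.8 fragments there, with a median of 195, yet 88 fell short and their median log2 difference relative to all genes was -2.12. Quantification mainly from spliced reads may account for it, but among 1201 genes of 5 or 6 exons the correlation with junctions per kilobase was 0.27, between the bounds set beforehand, and the same measure in sgNeg3 was -0.24. That explanation therefore stays open, and no other processing step was tested.

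G2/M and mitosis genes were lower in BRD8, RUVBL1 and RUVBL2 knockout. The list also passed as lower, by smaller means, in TRRAP, MORF4L2 and MORF4L1, and as higher in 6 others. None of these calls, including those in BRD8, RUVBL1 and RUVBL2, held in camera with an estimated correlation (adjusted p = 0.697 to 0.999 for the 6 higher). All 6 were compared with the same sgNeg2 pair, so they are not independent, and an unusual sgNeg2 pair was not tested. MORF4L1 and MORF4L2 likewise share the sgNeg3 pair with RUVBL1 and RUVBL2. A transcript length trend is argued against, because after its removal the list mean closest to 0 of BRD8, RUVBL1 and RUVBL2 was -0.67, in BRD8. In the BRD8 libraries the trend was small to begin with (-0.02 to 0.11 log2 units between short and long transcripts). Its removal could therefore hardly move that mean. Dependence on exon number was not tested as a cause of the fall in BRD8. An unusual sgNeg3 pair is argued against for RUVBL1 and RUVBL2, whose means against the 4 MORF4L1 and MORF4L2 libraries were -0.89 and -1.28. For BRD8 an unusual sgNeg1 pair cannot be told apart from the knockout, since the section has 1 control guide. Lowering in proportion to p53 activity stays open: over the 10 targets of the sgNeg2 section, the 2 list means correlated at r = -0.10 (permutation p = 0.79) and rho = -0.19 (p = 0.607; both 0.79 after adjustment), and at r = 0.13 without the 2 farthest targets.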

How the results depend on the processing

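The length trend removal, the rescaled comparison with all 8 sgNeg libraries, the shared spread on the genes of the main fit and both uses of the duplicated column were chosen after the data had been seen. The p53 induction count ran from 8792 to 11539 genes, and the share of its calls that were higher moved from 44.6% to 50.8% with median-ratio rescaling. Its p53 list, taken alone, kept its direction and passed under every alternative run, but not when adjusted over the 28 lists (adjusted p = 0.338 with an estimated correlation). Over all results, 229 of 269 alternative values of the p53 list, 710 of 906 of other lists and 2485 of 2719 of named genes kept their direction and side of the threshold. With an estimated correlation the p53 list means stayed as they were, by construction of that test. The calls ended in BRD8 (0.20), H2AZ (0.16), EP400 (0.07), ACTL6A (0.17), MRGBP (0.10), ING3 (0.20), DMAP1 (0.15), GAS41 (0.30), RUVBL1 (0.48) and RUVBL2 (0.54). They also ended for BRD8 minus MEAF6 (0.26), VPS72 (0.21), RUVBL1 (-0.28) and RUVBL2 (-0.32). With no filter EP400 (0.06, adjusted p = 0.113) and MRGBP (0.09, 0.0961) lost their call, as EP400 did with the spread shared and the genes chosen over all guide RNA libraries (0.06, 0.0557). On the genes of the main fit the shared spread left the EP400 call in place (0.07, 0.0445). Median-ratio rescaling gave list means of 0.07 in TIP60 and 0 in VPS72. The duplicated column used as MEAF6 guide 2 gave a list mean of 0.04 and MDM2 at 0.08, and used as VPS72 guide 2 a list mean of 0.05 and CDKN1A at 0.10. Calls in H2AZ were 1113 with the length trend removed, 146 with guide 1 alone and 247 with guide 2 alone, where fewer libraries entered, and 1050 with the shared spread on the genes of the main fit, or 1069 on genes chosen over all guide RNA libraries. In BRD8 these 2 fits gave 2007 and 1865. Where nothing else is said, the cause was not tested.

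Against all 8 sgNeg libraries as deposited, which mixes sections of different scale, BRD8 had 10497 calls (4% higher) and H2AZ 4662 (97.9% higher). The p53 list mean was -1.31 in BRD8 (adjusted p = 0.629, the call lost), 0.38 in TIP60, 0.39 in TRRAP, 0.37 in MEAF6 and 0.39 in VPS72. In BRD8, CDKN1A was -2.68, MDM2 -0.90, GDF15 -0.61, GADD45A -0.33, SESN2 -0.59, RPL8 -1.41, RPL38 -0.48, CRIM1 -0.21, ASAP1 -0.16, CTGF -1.42, USP18 0.49 and YEATS4 -0.87. SCG2 was 0.13 and S100A4 0.01 in H2AZ, CDKN1A was 0.72 in TIP60, 0.84 in MRGBP and 0.83 in VPS72, C1orf54 was 0.22 in ACTL6A, TRRAP was 0.11 in its own knockout, MDM2 was 0.42 in MEAF6, MORF4L1 was -0.23 and MORF4L2 0.58 in their own. After rescaling, BRD8 had 8453 and H2AZ 1828 calls. The list mean was then -0.19 in BRD8 (adjusted p = 0.516, the call lost), 0.24 in TIP60, 0.16 in TRRAP, 0.16 in MEAF6 and 0.17 in VPS72 (adjusted p = 0.0279, a call gained). In BRD8, CDKN1A was -1.30, TNC 0.43, CTGF -0.03, IRF7 0.35, DDX58 0.81, USP18 1.46 and ACTL6A 0.32. CDKN1A was 0.53 in TIP60, in MRGBP and in VPS72, MDM2 was 0.16 in MEAF6, MORF4L1 was -0.58 and MORF4L2 0.23 in their own. The cause was not tested beyond the scale, and the dependence of the sgNeg1 section on exon number remains after rescaling.

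Leaving out 1 library at a time gave 2325 to 3834 calls in BRD8 and 324 to 1176 in H2AZ. The p53 list mean then ran from 0.05 to 0.08 in EP400, -0.17 to 0.11 in TIP60, 0.07 to 0.26 in ACTL6A, 0.08 to 0.11 in MRGBP, -0.12 to 0.08 in TRRAP, 0.04 to 0.25 in DMAP1, 0 to 0.07 in MORF4L1 and -0.02 to 0.13 in MORF4L2. CDKN1A in MRGBP ran from -0.10 to 0, and MORF4L1 in its own knockout from -0.11 to 0.19. A knockout or control left with 1 library was assumed to vary like the others. With the replicate number as a block, 3662 genes were called in BRD8, 727 in H2AZ and 10263 in p53 induction. Correlations of same-numbered deviations ran from -0.03 to 0.03 in the BRD8 section, -0.47 to 0.58 in the sgNeg2 section (12 of 36 pairs over 0.1), -0.08 to 0.72 in the sgNeg3 section (6 of 10) and -0.28 to 0.31 in the H2AZ section, and the doxycycline pair had 0.04. In no section was every pair over 0.1, so the samples were treated as sharing only a number. The 6 pairs among MORF4L1, MORF4L2, RUVBL1 and RUVBL2 lay between 0.32 and 0.72, while sgNeg3 did not follow them (-0.08 to -0.02), and the block gave 4139 calls in RUVBL1 and 4585 in RUVBL2. Over the within-section alternatives, calls ranged from 9 to 1669 in EP400, 3428 to 5484 in TIP60, 0 to 712 in ACTL6A, 2 to 238 in MRGBP, 1 to 183 in ING3, 72 to 2657 in TRRAP, 0 to 77 in DMAP1, 0 to 1053 in GAS41, 0 to 24 in MEAF6, 0 to 21 in VPS72, 0 to 2 in MORF4L1, 0 to 1315 in MORF4L2, 859 to 6077 in RUVBL1 and 1652 to 6776 in RUVBL2. The ribosomal protein list in MORF4L2 went from 0.27 to 0.10 with the length trend removed (adjusted p from 8.84e-07 to 0.00139), and that in MRGBP from 0.14 to 0.01 (0.0184 to 0.814). The main calls of this list in MORF4L2 and MRGBP were both lost with an estimated correlation. Single sgNeg pairs of other sections and the mean of the 4 pairs as the contrast were not run, and the controls of BRD8 and the other knockouts are already separate. The sgNeg4 replicate 2 library had 4.3 fragments per kilobase at an FPKM of 1, the lowest of its section. Whether this limits H2AZ calls among weakly expressed genes was not tested.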

Other observations

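The NRF2 list and its tests were written after the largest changes of BRD8 and H2AZ had been seen, and its tests leave out the members seen by then, except that of a length trend, which covers all members.

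Metabolic and immune groups beyond those of the report also moved. In BRD8 knockout, 20 of 30 ribosome biogenesis genes rose and 1 fell (22 and 1 adjusted over the list alone; mean 0.27), 14 of 24 MYC targets rose and 1 fell (15 and 3; mean 0.27), and 8 of 12 genes of the NF-kB list rose and 1 fell (8 and 1; mean 0.42). Lysosome and autophagy genes (12 of 22 higher and 3 lower, 13 and 3 over the list alone; mean 0.24), ATF4 and unfolded protein response genes (14 of 24 higher and 4 lower, 15 and 4; mean 0.31) and immediate early genes (4 of 6 higher, 4 over the list alone; mean 0.52) rose too. G1/S and DNA replication genes (17 of 29 lower and 1 higher, 18 and 1 over the list alone; mean -0.29), DNA repair genes (9 of 13 lower and 1 higher, 9 and 1; mean -0.32) and cholesterol synthesis genes (11 of 22 lower and 1 higher, 11 and 2; mean -0.20) fell. Camera's adjusted p for these 9 lists lay between 2.46e-05 and 0.0242, and none held, with adjusted p = 0.374 with an estimated correlation for 7 of them, 0.452 for DNA repair and 0.521 for ATF4. In H2AZ knockout, cholesterol synthesis genes (4 of 23 higher, 10 adjusted over the list alone; mean 0.22), ribosome biogenesis genes (4 of 30 higher, 9 adjusted over the list alone; mean 0.23) and MYC targets (2 of 25 higher, 4 adjusted over the list alone; mean 0.17) passed. Those 3 did not hold, with adjusted p = 0.0884, 0.114 and 0.0967 with an estimated correlation.

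After p53 induction, cytosolic ribosomal protein genes fell (42 of 46, mean -0.54), as did ribosome biogenesis genes (24 of 30 lower and 4 higher, mean -0.78), and immediate early genes rose (13 of 16 higher and 2 lower, mean 1.09), each lost with an estimated correlation (adjusted p = 0.447, 0.338 and 0.338 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone. All 4 tested leukocyte and macrophage markers rose (4 adjusted over the list alone; mean 2.28, adjusted p = 0.0235, and 0.338 with an estimated correlation). Hypoxia and glycolysis genes (mean -0.37), mesenchymal glioblastoma genes (0.48) and markers of neurons (0.60), oligodendrocytes (-0.74), astrocytes (-0.09) and epithelium (-0.51) did not pass. Cholesterol synthesis genes had a mean of 0.36 and a median of -0.06, and ATF4 genes a mean of -0.16 and a median of 0.12.

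NRF2 target genes, which serve the oxidative stress response, were higher in BRD8 and H2AZ knockout. A list of 36 such genes was written down, and the 29 not yet seen were tested. In BRD8 their mean was 0.50 (16 of 24 tested higher and 2 lower; adjusted p over the 16 knockouts 5.53e-05, and 0.873 with an estimated correlation), with FTL at 1.67 ± 0.11, TALDO1 at 1.47 ± 0.14, TXN at 1.16 ± 0.10, SRXN1 at 1.15 ± 0.09 and GCLM at 1.03 ± 0.11, while AKR1C1 fell by 0.65. In H2AZ it was 0.34 (5 of 23 higher, with GCLM at 0.85 ± 0.12 and SRXN1 at 0.81 ± 0.09; adjusted p = 1.38e-07, and 0.341 with an estimated correlation) against separate controls. A length trend as the whole cause in BRD8 is argued against by its small size there (-0.02 to 0.11 log2 units between short and long transcripts). With so little to remove, the removal could hardly move the mean of all members (0.76 to 0.74) or of the unseen members (0.49 after it). In H2AZ the removal took the unseen members from 0.34 to 0.38 and from 5 to 11 of 23 called. A shared NRF2 response is thus a hypothesis that these lists are in line with, though 2 members also stand on other lists, FTL has near-identical copies, and GAS41 (0.42) and TIP60 (0.42) had similar means.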
